A study of Homo sapiens with 6 samples.

How the data were processed

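Polyadenylated RNA of 6 MDA-MB-231 libraries was measured by sequencing, 3 in the mimic group and 3 in the control group, per the labels. Reads were trimmed with cutadapt 1.9 and checked with FastQC, and the build was GRCh38 (hg38), per the submitters' processing notes. The aligner, the counting tool, the annotation release and the strandedness are not given in the sources used here, so reads of a gene and of an overlapping antisense gene could not be told apart. The deposited table, per the file headers, holds raw counts and FPKM for each library in 66381 rows. The deposited FPKM equal the count scaled by a fixed whole-number length per row and by the library's total count, within 5.5e-10 of a whole length. Identifiers are Ensembl genes (24487 rows, of which 24447 were found in GENCODE 29) or assembled loci (41894 rows). The 38792 assembled loci that name no gene held 2.46 to 2.70% of counts and were left out of library sizes and tests. The 1248 rows that name 2 or more genes held 10.2 to 11.0% of counts; they were tested and are written with a slash, but stay out of gene lists. Among counts of 1 to 10, even values were 1.17 times as frequent as odd ones. Library totals were 31643826 to 32363456 counts.

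Before the data were examined the design assumed FPKM and limma, with edgeR's quasi-likelihood test as the main test if raw counts were present. Counts were present, so edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) was used with TMM scaling, on rows with FPKM of at least 1 in at least 3 of 6 libraries (11260 rows), two-sided, with Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are mimic minus control, SE is the size of the log2 fold change divided by the square root of the F statistic, and FPKM are given as mean ± SD of 3 libraries. The common biological coefficient of variation was 14%. On simulated data for this comparison, with 200 changed genes among 11260, the test called 2% of genes changed 1.25-fold, 48% at 1.5-fold, 96% at 2-fold and 96% at 3-fold, with 10 false calls among 11060 unchanged genes. The data had more calls, 2506, which makes the Benjamini-Hochberg cutoff less strict, so small changes may be called more often than in the simulation. Every pair of libraries differed beyond sampling noise (chi-square per degree of freedom at least 27.1), so none was taken for a library deposited more than once; this does not show that they came from separate cultures.

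The 33 gene lists were written from textbook knowledge before the data were examined. Lists with at least 5 measured members (30) were tested with camera in limma 3.58.1 on log2(FPKM + 1) with a preset inter-gene correlation of 0.01. Of these, 16 passed with the preset correlation, 10 without mimic replicate 1, and 0 with an estimated correlation, where the lowest adjusted p was 0.11. In fry, which tests each list alone and was run on the same log2(FPKM + 1), 22 passed. List symbols were matched through the table's symbol or the current symbol, which added 6 members. Genes named in the text follow a rule fixed before the data were examined: the 10 higher and 10 lower single-gene rows with the largest fold change that passed, with no overlap between groups and a mean of at least 2 FPKM in the higher group, fixed MNK, p38, TNF and MIR5001 genes, and up to 4 members with the smallest p of each list that passed camera and up to 2 of other lists. Chance alone puts 3 libraries entirely above or below the other 3 in 10% of splits. MIR5001 was not among the gene names of the table used here. Members named because at most 5 of a list moved one way were chosen after their values were seen. Some genes that the rule names are not reported here.

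3′ UTRs came from GENCODE 29 transcripts, taking for each gene the basic protein-coding transcript with the longest 3′ UTR; 9057 tested genes had one. Differences in median were tested with 100000 permutations of fold changes across genes, and their bootstrap SE resampled genes. Both treat genes as independent, although genes can move together, and carry no spread between libraries. The planned match to miR-5001-5p, CCAGCCC, rests on a microRNA sequence recalled from memory and is reported in the closing section. All heptamers present in at least 50 genes (16109) were then scanned, after the data were seen. Alternatives were another normalization (scaling to library totals, median centring, quantile normalization), DESeq2 1.42.0, limma on log2(FPKM + pseudocount) with pseudocounts of 1, 0.5 and 0.1, other filters, robust fits, treat against a log2 fold change of 0.26, the replicate number as a block, each library left out in turn, and, added after seeing the data, fits over the 7501 genes with a 3′ UTR and neither heptamer, with unnamed loci, with single-gene rows, with DESeq2's size factors in edgeR and with a GC and length correction, and camera on log2 CPM. Tables were handled with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.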

Results

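RNA from MDA-MB-231 cells, a human triple-negative breast cancer line, was sequenced after transfection with a mimic, a synthetic RNA made to act like a microRNA. The mimic group had 3 libraries and the control group 3. The series title names miR-5001-5p, TNF-α and the MNK2a and p38 MAPK pathway, and the comparison asks which genes lie downstream of the mimic. The group labels say mimic and control and give neither oligonucleotide's sequence. Control libraries are titled minic_nc and mimic libraries minic, where nc may stand for a negative control oligonucleotide, which the labels do not spell out. Libraries held 31643826 to 32363456 counts each. Log2 CPM correlated across genes at 0.985 to 0.987 between libraries of a group and at 0.976 to 0.978 between groups, and the first principal component, with 43.7% of the variance, parted the groups. Nothing in the labels says that the replicates were separate cultures, so no p-value here reaches beyond these libraries, whose spread may be technical. Permutation p-values and bootstrap SE for heptamers were taken across genes and do not measure that spread.

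MKNK2 was lower in the mimic group. The gene encodes the kinase MNK2, which phosphorylates the cap-binding factor eIF4E. Its level was 5.62 ± 0.457 FPKM in mimic and 12.6 ± 2.65 in control (mean ± SD, n = 3 each), 2.13-fold lower, with a log2 fold change of -1.09 ± 0.15 (SE) and an edgeR adjusted p of 0.0034. All 3 mimic libraries, with 1031, 871 and 948 counts, lay below the 3 control libraries, with 1842, 1943 and 2617. The gene (ENSG00000099875) lies on chromosome 19 from 2037465 to 2051244 on GRCh38, and values per gene cannot tell the MNK2a and MNK2b isoforms apart. An exact two-sided permutation test on this gene alone gave p = 0.1, the smallest that 3 against 3 libraries allow.

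**Figure D1:**
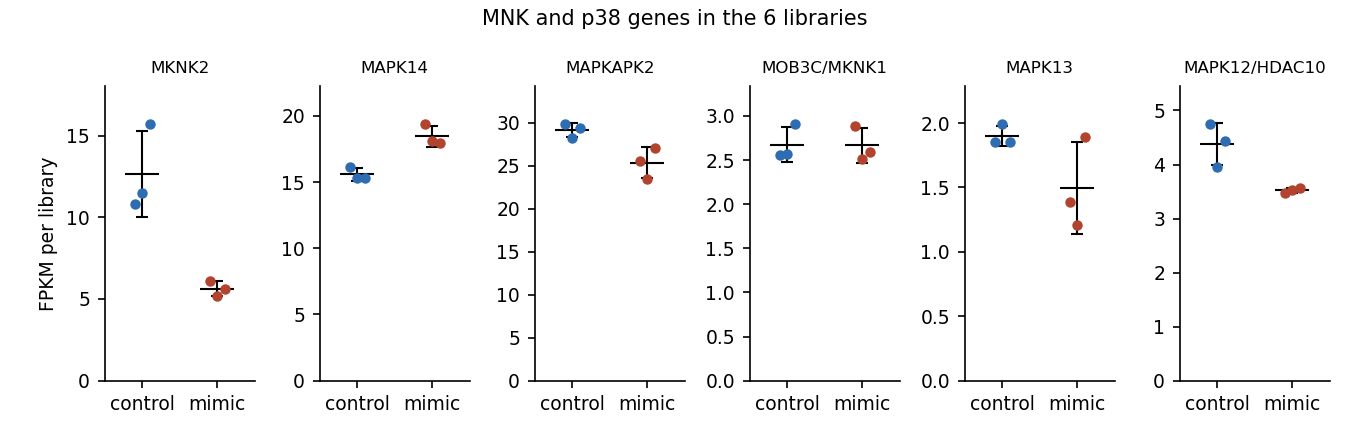
FPKM of MKNK2, MAPK14, MAPKAPK2, MAPK13 and the merged loci MOB3C/MKNK1 and MAPK12/HDAC10 in each library. Points are libraries, horizontal marks group means and bars 1 SD (n = 3 per group), and each panel has its own axis from 0. MKNK2 averaged 12.6 FPKM in control and 5.62 in mimic, while MAPK14 averaged 15.6 and 18.4.

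Of the p38 genes measured alone, MAPK14 rose and MAPK13 did not pass the test. MAPK14, which encodes p38α, rose from 15.6 ± 0.522 to 18.4 ± 0.782 FPKM (log2 0.32 ± 0.05, edgeR adjusted p = 0.00629). MAPKAPK2, which encodes the p38 substrate kinase MK2, had a log2 fold change of -0.12 ± 0.07 (adjusted p = 0.229) and MAPK13 one of -0.26 ± 0.17 (adjusted p = 0.3), which reached an adjusted p of 0.022 without mimic replicate 3 (log2 -0.47). MKNK1 and MAPK12 were counted only in loci merged with a neighbour, MOB3C/MKNK1 (log2 0.07 ± 0.09, adjusted p = 0.59) and MAPK12/HDAC10 (log2 -0.24 ± 0.08, adjusted p = 0.075). MAPK12/HDAC10 passed without control replicate 2 (log2 -0.30, adjusted p = 0.044) and with libraries scaled to their totals (log2 -0.32, adjusted p = 0.028), and the sign of MOB3C/MKNK1 flipped under that scaling. MAPK11 and TNF were below the expression filter: MAPK11 had 4 counts in control replicate 3 and 0 in the other libraries, and TNF had 4, 3 and 0 counts in control and 15, 4 and 6 in mimic.

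Of 31 measured members of the p38 MAPK pathway list, 10 were higher and 3 lower (10 and 3 adjusted over the list alone). TAB3, an adaptor of the kinase TAK1, rose 2.07-fold (log2 1.05 ± 0.07, edgeR adjusted p = 0.000213) and DUSP1, a phosphatase that inactivates MAP kinases, 1.75-fold (0.81 ± 0.07, adjusted p = 0.000421). The 3 lower members were MKNK2, TAB2 (log2 -0.76 ± 0.15) and TAB1 (-0.27 ± 0.07). The list did not pass camera (adjusted p = 0.14) but passed upward in fry, which tests the list alone (adjusted p = 0.031). In the MNK and eIF4E list 2 of 13 members were higher, EIF4G2 (log2 0.28 ± 0.06) and EIF4E2 (0.32 ± 0.08), and 1 was lower, MKNK2, with the same counts adjusted over the list alone. Its camera test gave an adjusted p of 0.97, while it passed downward in fry (adjusted p = 0.034). Fry was run on log2(FPKM + 1), scaled to library totals, where the median log2 fold change of all genes was -0.075. The list's median was -0.05 with counts scaled to totals, so its downward call cannot be told from the scaling. With TMM the list's median of 0.03 and mean of -0.02 differed in sign. In the MAPK and PI3K core list 7 of 38 members were higher and 4 lower (9 and 5 adjusted over the list alone; camera adjusted p = 0.42). NRAS rose 3.28-fold from 29.6 to 92.0 FPKM (log2 1.71 ± 0.05, adjusted p = 1.1e-05) and FOXO3 1.65-fold, while RPTOR (log2 -0.48 ± 0.04), RPS6KA1 (-0.38), MAPK3 (-0.26) and SOS1 (-0.24) fell. The calls of TAB1, EIF4G2, EIF4E2, MAPK3 and SOS1 ended in at least 3 of the 6 fits that left out 1 library, with adjusted p up to 0.097.

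Across the transcriptome 2506 of 11260 tested genes differed, 1534 higher and 972 lower in mimic (edgeR, Benjamini-Hochberg), and 150 of the higher and 35 of the lower changed 2-fold or more. GLO1, which encodes the methylglyoxal-clearing enzyme glyoxalase I, rose 6.06-fold from 23.2 ± 3.60 to 133 ± 32.5 FPKM (log2 2.60 ± 0.19, adjusted p = 0.000255). CCNA2, which encodes cyclin A2, rose 4.54-fold from 12.5 ± 0.227 to 53.9 ± 3.88 FPKM (log2 2.18 ± 0.07, adjusted p = 2.2e-05). CXCL8, which encodes the chemokine interleukin-8, rose 3.59-fold from 233 ± 12.8 to 791 ± 58.5 FPKM (log2 1.84 ± 0.07, adjusted p = 2.4e-05). The other seven of the 10 highest were CMTM6 (4.10-fold), ADAMTS1 (3.85-fold), MTMR6 (3.74-fold), NEK2 (3.65-fold), ATXN10 (3.56-fold), IL11 (3.52-fold) and PLOD2 (3.46-fold). All 10 carry AGTACAA or GTACAAA in the annotated 3′ UTR, against 17.2% of the tested genes with one. These heptamers were picked by a scan of the same fold changes, so this count is not independent support for them. Scaling libraries to their totals turned the split: the share of changed genes that were higher fell from 61.2% to 38.5%, with 1134 higher and 1809 lower. It was 39.8% in limma on log2(FPKM + 1), with 1707 lower, and 51.2% with quantile normalization. The total fell to 1576 without control replicate 3, and the lower count to 569, 588, 503 and 642 without control replicates 1, 2 and 3 and mimic replicate 2.

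PDE7B, which encodes a cAMP phosphodiesterase, fell 3.77-fold from 2.32 ± 0.148 to 0.583 ± 0.143 FPKM (log2 -1.92 ± 0.19, edgeR adjusted p = 0.000909). NUDT1, which encodes an enzyme that clears oxidised nucleotides, fell 3.41-fold from 14.9 ± 0.653 to 4.14 ± 0.419 FPKM (log2 -1.77 ± 0.11, adjusted p = 0.000115). IFIT1, an interferon-induced antiviral gene, fell 3.40-fold (log2 -1.77 ± 0.16, adjusted p = 0.000584). The other seven were MCRIP1 (log2 -1.70), NUDT4 (-1.61), TPRG1L (-1.59), LYRM7 (-1.43), AC012513.3 (-1.36), ARID3A (-1.33) and AC009414.2 (-1.31). NUDT4 has a near-identical copy, NUDT4B, that could share its reads. LYRM7 and ARID3A each lost the call in 5 of 6 fits without 1 library: only without control replicate 2 did LYRM7 keep it, and only without mimic replicate 1 did ARID3A, with adjusted p up to 0.099 and 0.074 in the others.

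**Figure D2:**
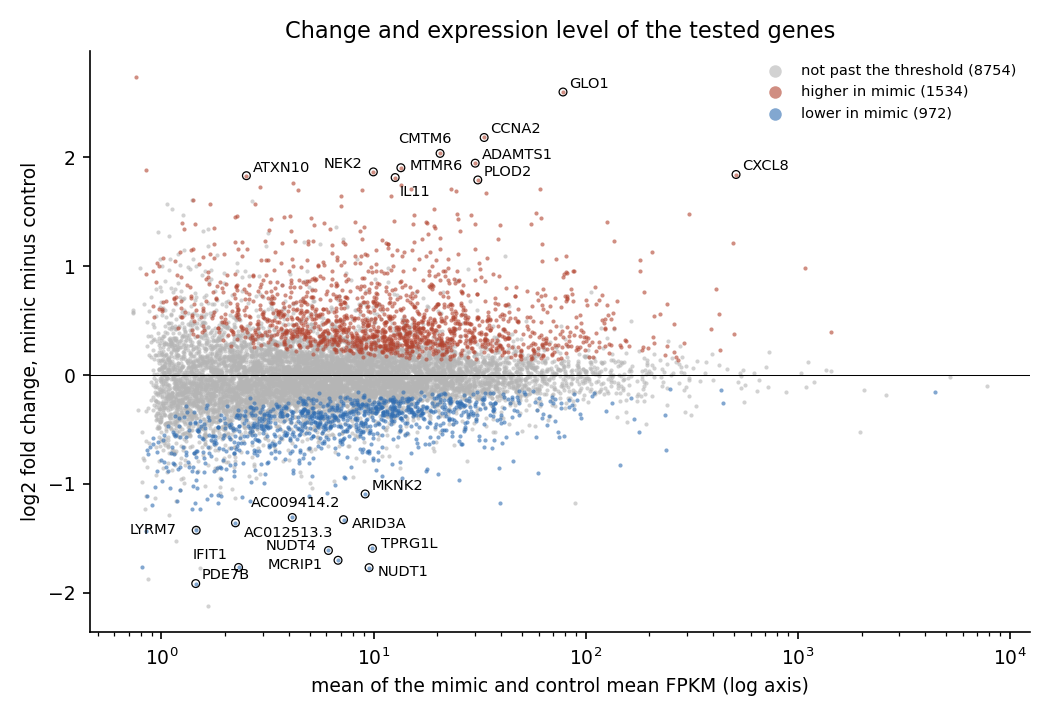
Log2 fold change, mimic minus control, of the 11260 tested genes against the mean of the group means in FPKM (log axis). Red points are the 1534 genes higher in mimic, blue the 972 lower and grey the rest; MKNK2 and the 20 named genes are circled.

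Of 41 measured members of the G2/M and mitosis list 29 were higher and 0 lower (32 and 0 adjusted over the list alone), with a median log2 fold change of 0.44. Besides CCNA2, TOP2A, which encodes topoisomerase IIα, rose 2.71-fold from 34.3 to 88.3 FPKM (log2 1.44 ± 0.06, edgeR adjusted p = 5.3e-05), the kinase gene PBK 2.79-fold (1.48 ± 0.09) and CKS2, which encodes a subunit of cyclin-dependent kinases, 2.34-fold (1.23 ± 0.08). All 4 carry AGTACAA or GTACAAA. The list passed camera at an adjusted p of 6.8e-17, and the adjusted p = 0.11 with an estimated correlation. Of 43 G1/S and replication genes 12 were lower and 4 higher (16 and 4 adjusted over the list alone; camera adjusted p = 0.0033, and adjusted p = 0.11 with an estimated correlation). CDC25A, a phosphatase that starts S phase, fell 1.74-fold (log2 -0.80 ± 0.10) and the histone chaperone gene CHAF1A 1.48-fold (-0.57 ± 0.07). The higher members include CDK6 (log2 0.74), POLA1 (0.89) and TYMS (0.22), of which TYMS lost the call in 4 fits without 1 library (adjusted p up to 0.077). The list of replication-dependent histone genes was written as a check on RNA quality, and 12 of its 55 genes were measured in this polyadenylated RNA. Of these 12 genes 3 were higher and 0 lower (3 and 0 adjusted over the list alone), HIST1H2BK (log2 0.30), HIST1H1C (0.26) and HIST1H2AG (0.68), with HIST1H2BJ at 0.68 ± 0.22 (adjusted p = 0.0688). HIST1H1C and HIST1H2AG each lost the call in 5 fits without 1 library (adjusted p up to 0.085). That list's camera adjusted p of 0.036 became 0.095 without control replicate 1, 0.062 without mimic replicate 1, 0.063 with median centring and 0.12 on log2 CPM, and the adjusted p = 0.3 with an estimated correlation.

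**Figure D3:**
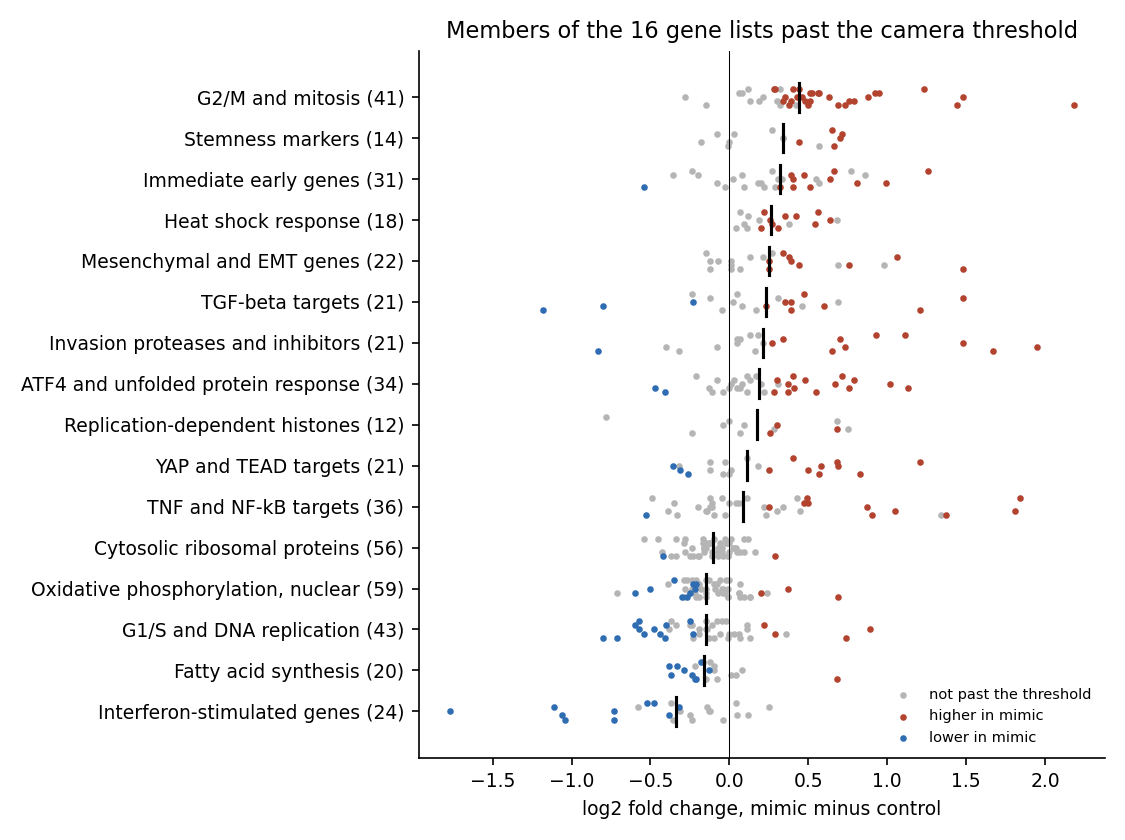
Log2 fold changes, mimic minus control, of the measured members of the 16 gene lists that passed camera, 1 point per gene, with the number measured in brackets and a vertical mark at the median. Red points are genes higher in mimic, blue lower and grey not past the threshold. The median is 0.44 for the mitotic list and -0.34 for interferon-stimulated genes.

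In the list of invasion proteases and inhibitors 10 of 21 members were higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 9.7e-05, and adjusted p = 0.11 with an estimated correlation). ADAMTS1, a secreted metalloprotease gene, rose 3.85-fold to 47.4 FPKM, ADAM9, which encodes a membrane metalloprotease, 3.19-fold (log2 1.67 ± 0.05), and PLAU, which encodes urokinase, 1.57-fold (0.65 ± 0.04). MMP3 was the lower member (log2 -0.83 ± 0.24), and its call ended in 5 fits without 1 library (adjusted p up to 0.13). Of 22 mesenchymal genes 9 were higher and 0 lower (12 and 0 adjusted over the list alone; camera adjusted p = 0.00081, and adjusted p = 0.13 with an estimated correlation). They include ITGB1, which encodes integrin β1 (2.08-fold), MMP14 (1.27-fold) and VIM, the vimentin gene (1.30-fold, 449 to 553 FPKM). Of 15 epithelial genes 3 were higher, among them LAMB3 (log2 0.35) and KRT18 (0.55), and 3 lower, CLDN1 (-0.42), JUP (-0.35) and OCLN (-0.93), with 5 and 3 adjusted over the list alone (camera adjusted p = 0.38). JUP and OCLN lost the call in at least 5 fits without 1 library (adjusted p up to 0.086).

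TGF-β targets held 8 higher and 3 lower of 21 (10 and 4 adjusted over the list alone; camera adjusted p = 0.029, and adjusted p = 0.49 with an estimated correlation). CTGF, current name CCN2 and encoding a matricellular protein, rose 2.31-fold from 311 to 682 FPKM (log2 1.21 ± 0.05) and SMURF2 1.38-fold, while COL1A1 (log2 -1.18 ± 0.12), ID3 (-0.80) and SMURF1 (-0.23) fell. Of 21 YAP and TEAD targets 9 were higher and 3 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.048, and adjusted p = 0.49 with an estimated correlation). F3, the tissue factor gene, rose 1.78-fold, NT5E 1.60-fold and CYR61, current name CCN1, 1.32-fold, while MYOF (log2 -0.31), AMOTL1 (-0.26) and NUAK2 (-0.36) fell. The TGF-β call ended without control replicate 2 (adjusted p = 0.061), without mimic replicate 1 (0.065) and with quantile normalization (0.053). The YAP call ended without control replicates 1 and 2 (0.063 and 0.12) and mimic replicates 1 and 3 (0.069 and 0.054), with median centring (0.068) and quantile normalization (0.19), with no filter (0.065), over genes of at least 5 FPKM (0.12) and on log2 CPM (0.062). The CYR61 call ended with quantile normalization. ID3, SMURF1 and NUAK2 lost their calls in at least 3 fits without 1 library (adjusted p up to 0.11). Of 14 stemness markers 5 were higher and 0 lower (5 and 0 adjusted over the list alone): SOX9 (log2 0.65), JAG1 (0.71), CD44 (0.44), HES1 (0.70) and CD24 (0.66). Camera gave an adjusted p of 0.023, which was 0.057 without mimic replicate 1 and 0.15 over genes of at least 5 FPKM, and the adjusted p = 0.17 with an estimated correlation; HES1 and CD24 lost their calls in at least 4 fits without 1 library (adjusted p up to 0.13). Of 21 collagen and matrix genes 4 were higher, among them FBN1 (log2 1.39), LAMB3 and LAMB1 (0.37), and 2 lower, COL1A1 and LAMA3 (-0.23), with the same counts adjusted over the list alone (camera adjusted p = 0.97). LAMB1 and LAMA3 lost the call in 4 fits each without 1 library (adjusted p up to 0.09).

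Of 36 measured TNF and NF-kB targets 10 were higher and 1 lower (11 and 4 adjusted over the list alone). Beside CXCL8, the survival gene BCL2A1 rose 2.59-fold (log2 1.37 ± 0.10, edgeR adjusted p = 0.000228), IL11 3.52-fold from 5.84 to 19.5 FPKM, and CYLD, which encodes a deubiquitinase that restrains NF-kB, 1.87-fold. The 1 lower member was the cytokine gene IL6, 1.44-fold from 89.5 ± 5.03 to 58.8 ± 1.84 FPKM (log2 -0.53 ± 0.05, adjusted p = 0.00102). The list's camera adjusted p was 0.045; it was 0.094 without control replicate 2, 0.1 without mimic replicate 1, 0.088 without mimic replicate 3, 0.079 with median centring, 0.18 with quantile normalization, 0.099 over genes of at least 5 FPKM, 0.082 on log2 CPM and 0.097 over genes with a 3′ UTR that has neither AGTACAA nor GTACAAA, and the adjusted p = 0.49 with an estimated correlation. Immediate early genes held 11 higher and 1 lower of 31 (14 and 2 adjusted over the list alone; camera adjusted p = 0.00074, and adjusted p = 0.11 with an estimated correlation). EGR1 rose 2.40-fold (log2 1.26 ± 0.12) and JUN 1.56-fold (0.64 ± 0.04), and SRF, which encodes a transcription factor that drives many of them, fell 1.45-fold (-0.54 ± 0.04).

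Of 24 measured interferon-stimulated genes 10 fell and 0 rose (12 and 0 adjusted over the list alone), with a median log2 fold change of -0.34. After IFIT1, IFIT3 fell 2.16-fold from 6.87 to 3.01 FPKM (log2 -1.11 ± 0.11, edgeR adjusted p = 0.000894), SAMD9 1.66-fold (-0.73 ± 0.11) and UBE2L6, which encodes an enzyme that attaches ISG15, 1.44-fold (-0.52 ± 0.08). The list passed camera at an adjusted p of 0.00022, and the adjusted p = 0.17 with an estimated correlation. Of 11 genes of MHC class I presentation 3 were higher, TAP2 (log2 0.60), PDIA3 (0.44) and ERAP1 (0.71), and 1 lower, PSMB8 (-0.37), with 3 and 3 adjusted over the list alone (camera adjusted p = 0.68).

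Of 34 ATF4 and unfolded protein response genes 14 were higher and 2 lower (14 and 2 adjusted over the list alone; camera adjusted p = 0.00074, and adjusted p = 0.17 with an estimated correlation). HSPA5, which encodes the endoplasmic reticulum chaperone BiP, rose 2.19-fold from 133 to 276 FPKM (log2 1.13 ± 0.06, edgeR adjusted p = 9.2e-05), HSP90B1 1.46-fold, PDIA6 1.32-fold and CEBPG 1.59-fold, while DDIT4 (log2 -0.41) and SLC7A11 (-0.47) fell. Heat shock genes held 10 higher and 0 lower of 18 (11 and 0 adjusted over the list alone; camera adjusted p = 3.4e-05, and adjusted p = 0.11 with an estimated correlation), among them the chaperone genes HSPD1 (1.56-fold), HSP90AA1 (1.48-fold), HSPA4 (1.24-fold) and BAG3 (1.46-fold). Of 19 NRF2 targets 1 was higher, GSR (log2 1.17), and 5 lower, among them TKT (-0.26), SLC7A11, ME1 (-0.24) and MT1E (-0.57), with 2 and 5 adjusted over the list alone (camera adjusted p = 0.29). Of 20 p53 targets 3 were higher, TNFRSF10A (log2 0.71), GADD45A (0.50) and POLH (0.40), and 2 lower, FDXR (-0.54) and BAX (-0.45), with the same counts adjusted over the list alone (camera adjusted p = 0.8). Of 29 apoptosis regulators 5 were higher, among them BCL2A1, TNFRSF10A, MCL1 (log2 0.66) and BIRC2 (1.05), and 2 lower, CASP9 (-0.45) and BAX, again with the same counts adjusted over the list alone (camera adjusted p = 0.23). ME1, MT1E, FDXR, BAX and CASP9 lost their calls in at least 4 fits without 1 library (adjusted p up to 0.11).

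Of 20 fatty acid synthesis genes 9 were lower and 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 0.00074, and adjusted p = 0.11 with an estimated correlation). ACSS2 fell 1.29-fold (log2 -0.37 ± 0.05), ELOVL5 1.30-fold (-0.38 ± 0.06), ACLY 1.17-fold and FASN, which encodes fatty acid synthase, 1.16-fold from 181 to 148 FPKM, and GPAM was the higher member (log2 0.68). ACLY, FASN and GPAM lost the call in at least 2 fits without 1 library (adjusted p up to 0.065). In the cholesterol list 5 of 23 were higher, among them FDPS (log2 0.80), ACAT2 (0.28) and MSMO1 (0.29), and 3 lower, among them DHCR7 (-0.32) and MVK (-0.49), with 6 and 3 adjusted over the list alone (camera adjusted p = 0.66). MVK lost the call in 5 fits without 1 library (adjusted p up to 0.13). Of 31 glycolysis and hypoxia genes 7 were higher, led by PDK1 (log2 0.55) and NDRG1 (0.54), and 3 lower, PFKL (-0.28), PFKM (-0.31) and ALDOC (-0.29), with 9 and 5 adjusted over the list alone (camera adjusted p = 0.19). These 3 lost the call in at least 1 fit without 1 library (adjusted p up to 0.1).

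Of 59 nuclear genes of oxidative phosphorylation 9 were lower and 3 higher, but only 2 and 1 adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.49 with an estimated correlation). NDUFA2 (log2 -0.60 ± 0.13) fell, and NDUFB5 (0.69 ± 0.10), UQCRFS1 (0.37) and SDHB (0.20) rose, of which NDUFB5 alone kept its call in all 6 fits without 1 library (adjusted p up to 0.13 for the others). Among 5 mitochondrially encoded mRNAs MT-CO1 was lower (log2 -0.16 ± 0.04, edgeR adjusted p = 0.0371; 1 adjusted over the list alone) and MT-CO2 had -0.10 ± 0.04 (adjusted p = 0.0913); the MT-CO1 call ended in 5 fits without 1 library, and camera gave an adjusted p of 0.18. Of 56 cytosolic ribosomal protein genes 1 was lower and 1 higher, RPL29 (log2 0.29), and 0 passed when adjusted over the list alone, with a list median of -0.11 (camera adjusted p = 0.0019, and adjusted p = 0.65 with an estimated correlation). RPL37A had -0.54 ± 0.18 (adjusted p = 0.0682) and RPS28 -0.43 ± 0.14 (adjusted p = 0.071). The list call ended without mimic replicate 1 (adjusted p = 0.057) and in fry, which tests the list alone (0.13), and the RPL29 call without control replicates 1 and 3, and such genes have many pseudogene copies that could share their reads.

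Of 23 genes of the microRNA machinery 4 were higher, TNRC6C (log2 0.88), AGO4 (0.65), CNOT7 (0.21) and PAN2 (0.32), and 2 lower, ADAR (-0.25) and MOV10 (-0.34), with 5 and 2 adjusted over the list alone (camera adjusted p = 0.53). AGO4, CNOT7 and PAN2 lost the call in at least 3 fits without 1 library (adjusted p up to 0.11). Of 9 luminal breast markers 2 were higher, XBP1 (log2 0.79) and KRT18, and 0 lower (3 and 0 adjusted over the list alone; camera adjusted p = 0.16). Lists for other cell types had too few members above the expression filter for a test, and with no filter camera gave adjusted p of 0.6 for haematopoietic, 0.65 for fibroblast and 0.22 for endothelial markers. The haematopoietic list had LCP1 (log2 -0.04 ± 0.04, edgeR adjusted p = 0.506), the fibroblast list COL1A1, lower as above, and ACTA2 (-0.12 ± 0.15, adjusted p = 0.606), and the endothelial list ROBO4, which rose (0.44 ± 0.06, adjusted p = 0.00359), and ESAM (0.14 ± 0.07, adjusted p = 0.211).

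Genes with AGTACAA or GTACAAA in the 3′ UTR made up much of the higher set, a measure chosen after the data were seen. They were 580 of 1392 higher genes with an annotated 3′ UTR (41.7%), 40 of 833 lower genes (4.8%) and 1556 of all 9057 (17.2%). Among genes higher by 2-fold or more they were 100 of 129 (77.5%). CCNA2 has AGTACAAA on chromosome 4 at 121817516 to 121817523, in exon 8 of 8, ADAMTS1 on chromosome 21 at 26837110 to 26837117, and GLO1 at 2 places on chromosome 6, 38676370 to 38676377 and 38676846 to 38676853, all on GRCh38 and within the 3′ UTR. In the MAPK and PI3K list 15 of 38 members carried a heptamer, among them all 7 higher members and 0 of the 4 lower. In the p38 MAPK list 8 of 31 members carried one, among them 4 of the 10 higher and 1 of the 3 lower, TAB2. In the mitotic list 5 of the 29 higher members carried a heptamer, and the 36 members with neither had a median of 0.41. Among the 10 interferon-stimulated genes that fell 0 carried one, which is little different from the 4.8% of all lower genes. Of the 7501 genes with a 3′ UTR and neither heptamer 812 were higher and 793 lower. When these 7501 genes were fitted and scaled alone, which also left out genes with no annotated 3′ UTR, 972 were higher and 653 lower. Of the 6292 with neither heptamer in the 3′ UTR or the coding sequence 552 were higher and 706 lower in the fit of all genes.

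**Figure D4:**
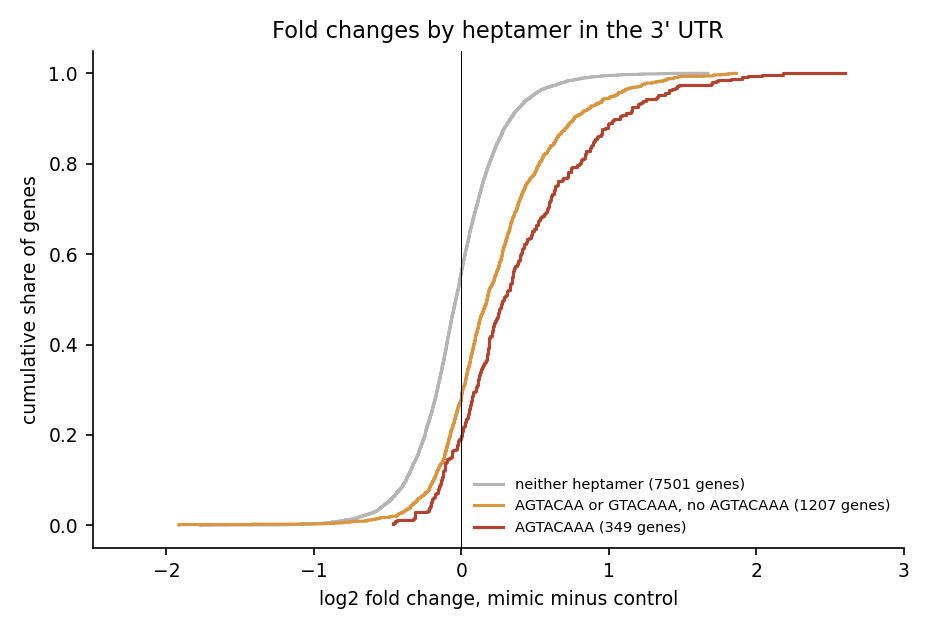
Cumulative share of genes against log2 fold change, mimic minus control, for genes with AGTACAAA in the 3′ UTR (349), with AGTACAA or GTACAAA but not AGTACAAA (1207) and with neither heptamer (7501). Medians are 0.289, 0.176 and -0.037, so the curves lie further right with the longer match.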

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

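The assembled loci that name no gene were outside the comparisons and drew attention because some differed from the control libraries. When they were included, a choice made after seeing the data, 59 of 1130 such loci above the expression filter were higher in mimic and 50 were lower (edgeR, Benjamini-Hochberg adjusted p under 0.05, 3 libraries per group). What they transcribe was not analysed here.

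The count of 2506 changed genes was set beside the other splits of the 6 libraries into 3 and 3, of which the highest called 7 genes. The real split was the 1 of 10 with as many, and 10 splits are too few for a share under 0.05.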

How the results depend on the processing

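Fits over the 7501 genes with a 3′ UTR that has neither AGTACAA nor GTACAAA, called heptamer-free genes, with unnamed loci, with loci naming 1 gene, with DESeq2's size factors in edgeR, with log2 CPM for the lists and with a GC and length correction were chosen after the data were seen; the other alternatives were chosen before.

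MKNK2 kept its direction and call in all 23 alternatives, with log2 fold changes of -1.20 to -0.91 when 1 library was left out and -1.17 to -0.98 otherwise, and adjusted p up to 0.017. Of 2506 changed genes, 185 (150 higher, 35 lower) also changed 2-fold or more, and 822 (624 higher, 198 lower) passed treat, both stricter by construction. Over the heptamer-free genes, a fit that also leaves out genes with no annotated 3′ UTR and so tests fewer genes, 1625 changed and 972 were higher, against 812 higher and 793 lower of these genes in the fit of all genes. The lower count of 972 rose to 1809 when libraries were scaled to their totals, which moved the median of all genes from -0.014 to -0.094, and to 1707, 1698 and 1680 in limma on deposited FPKM, which are also scaled to totals, with pseudocounts of 1, 0.5 and 0.1. Of the 2506 genes 2106 were also called when libraries were scaled to their totals. With fewer samples, 1 library left out, the total was 1576 to 2222 with 1073 to 1368 higher and 503 to 854 lower.

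Of 3572 values of named genes under alternatives, 3153 kept direction and side of the threshold, 387 lost the call, 28 gained one and 4 turned direction. The 4 were all of MOB3C/MKNK1, which never passed: -0.0076 scaled to totals, and -0.0033, -0.0038 and -0.0043 in limma with pseudocounts of 1, 0.5 and 0.1. Its log2 fold change of 0.07 is smaller than the shift of all genes under that scaling, from -0.014 to -0.094, and close to that in limma, to -0.075. Of 149 named genes with a call, 104 kept it in all 6 fits without 1 library, as did 18 of the 20 with the largest fold changes. Quantile normalization ended 15 calls of named genes, the fit with no filter 20 and treat 71.

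Of 30 lists 16 passed camera, and 10 to 16 did with 1 library left out, the fewest without mimic replicate 1. With an estimated correlation 0 passed, and 0 also over the heptamer-free genes, while 22 passed in fry. Of 566 list values 472 kept direction and side, 60 lost the call and 7 gained one, all 7 in fry. Among the 7 were the p38 MAPK list (up, adjusted p = 0.031) and the MNK and eIF4E list (down, adjusted p = 0.034). Another 27 turned direction, all in lists that had no call, and the cause was not tested. For the MNK and eIF4E list the adjusted p were 0.88 with no filter, 0.84 scaled to totals, 0.73 with median centring, 0.55 on log2 CPM, and 0.84 over the heptamer-free genes (0.89 with an estimated correlation), and 0.85 to 0.99 with 1 library left out. For MHC class I they were 0.99 in fry, 0.81 with no filter, 0.87 over genes of at least 5 FPKM, 0.94 with quantile normalization and 0.84 over the heptamer-free genes (0.89 with an estimated correlation). For collagens they were 0.99 in fry, 0.88 with no filter, 0.77 at 5 FPKM and 0.61 to 0.97 with 1 library left out. For p53 targets they were 0.97 with no filter, 0.72 at 5 FPKM and 0.86 over the heptamer-free genes (0.89 with an estimated correlation). The microRNA machinery turned in fry (0.42) and over the heptamer-free genes (1 with either correlation), and MAPK and PI3K over the heptamer-free genes (0.31, and 0.67 with an estimated correlation).

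The CCAGCCC difference in median of -0.05 became -0.009 with the GC and length correction and was -0.065 to -0.039 with 1 library left out. At this depth and with 3 libraries per group, on simulated data for this comparison with 200 changed genes, 48% of genes changed 1.5-fold and 96% of those changed 2-fold were called.

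With the replicate number as a block 1922 genes changed (1250 higher, 672 lower), MKNK2 had -1.08 (adjusted p = 0.013), 16 lists passed and 24 named genes lost their call. Deviations of libraries with the same number correlated at -0.009, 0.06 and -0.05, and not every library correlated best with its own number. No pairing by number was visible, but 3 libraries per group cannot exclude that equal numbers mark a shared culture or day.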

Other observations

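Tests of the AGTACAA and GTACAAA heptamers, of the mitotic list's dependence on them and all GC and length corrections were chosen after the results were seen; the CCAGCCC comparison, its other site types and its rank by difference in median were planned, and the count of matches per gene was not.

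Of all 16109 heptamers scanned in 3′ UTRs, GTACAAA and AGTACAA, which overlap as AGTACAAA, ranked first and next for higher genes by adjusted z (22.2 and 20.7), with adjusted mean log2 differences of 0.238 and 0.248 once GC content, 3′ UTR length and expression level were regressed out. These trends do not account for the whole shift: the best other rearrangement of the same bases reached 0.111, and the difference in median of 0.234 ± 0.015 (bootstrap SE) stayed at 0.16 ± 0.014 after a GC and length correction. Genes with AGTACAAA had a median 0.113 ± 0.036 above the 1207 genes with AGTACAA or GTACAAA but not AGTACAAA (permutation p = 6e-05). Pairing to a small RNA with UUGUACU at nucleotides 2 to 8 would need such a difference. Both heptamers were picked from these same fold changes, and the contrast was not corrected for GC or length, so it is not independent support. Genes with a match in the coding sequence alone also had a higher median, by 0.135 ± 0.01. Part of the shift may thus follow base composition, which this value cannot tell from pairing within the coding sequence. A candidate explanation, as a hypothesis, is that such an oligonucleotide repressed these genes in the control libraries, but the labels do not give the control's sequence and, without an untransfected library, which group moved stays open, as does a mimic effect through another route.

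The planned miR-5001-5p comparison gave a small shift: 2094 genes with CCAGCCC in the 3′ UTR had a median of -0.045 against 0.005 in 6963 without, a difference of -0.05 ± 0.0087 (permutation p = 1e-05, the smallest that 100000 permutations can give). By that difference CCAGCCC ranked 18 of the 42 rearrangements of its bases. By z, a measure added later that grows with the number of genes, it ranked 2 of 42, and by adjusted z 3 of 42. Its adjusted mean difference was -0.024, against -0.046 for the lowest other rearrangement. Pairing to this seed and a composition effect therefore cannot be told apart here. After the GC and length correction the difference in median was -0.009 ± 0.0073 (permutation p = 0.24). The call ended because the shift shrank, not because its spread grew, as it would under a GC and length trend. The longer match CCAGCCCA gave -0.043 ± 0.01, CAGCCCA -0.038 ± 0.0093 and CCAGCCC in the coding sequence -0.04 ± 0.008, none larger than the -0.05 of CCAGCCC, while medians were -0.035, -0.063, -0.057 and -0.076 for genes with 1, 2, 3 and 4 or more matches. MKNK2 has 2 such matches in its 3′ UTR, in exon 13 of 13 on chromosome 19 at 2039005 to 2039011 and 2039161 to 2039167, and these data do not test whether either acts.

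The mitotic list's rise may not come from these heptamers in 3′ UTRs: its 36 members with neither there had a median log2 fold change of 0.41 (95% bootstrap interval 0.32 to 0.51). Members with a match in the coding sequence were not taken out. Over all genes, those with a match in the coding sequence alone had a median of 0.076. A GC and length trend does not account for the rise either, since the median of the members was also 0.41 (0.28 to 0.51) after that correction. An effect of either oligonucleotide on cell cycle position stays open and was not tested.

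Of all heptamers, GGTCGGT had the lowest adjusted z for lower genes (-4.8), with an adjusted mean difference of -0.151 over 118 genes. CCTCCCT had the same z after rounding, with an adjusted mean difference of -0.039 over 2277 genes. Both were picked as extremes of the 16109 heptamers scanned, and no test allowed for that number.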
